A study of Macaca fascicularis with 1154 samples.

How the data were processed

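Each sample was 1 cell of a cultured cynomolgus monkey embryo. Per the labels' protocols, embryos were digested with trypsin, cells were picked with a mouth pipette under a stereomicroscope, and SMART-seq2 libraries were made for the BGISEQ-500 sequencer. Per the submitters' processing notes, STAR 2.3.4 and RSEM were used. The genome build and annotation are not given in the sources used here. The deposited values were estimated counts per gene that need not be whole: 2.23% of all values and 9.59% of those above 0 were not whole, with a tolerance of 1e-06. They were not normalized and were rounded to whole numbers for the count tests. SMART-seq2 has no molecular identifiers, so counts are of reads and intervals cover counting error only. Each of the 600 columns carried the title of 1 sample.

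All 28592 rows had an Ensembl-type ID for this species, and 0 of them were found in any field of the gene table given with the data. The files do not pair the IDs with names. The comparisons of epiblast-like, endoderm-like, trophoblast-like, amnion-like, extraembryonic mesenchyme-like, gastrulating-like and primordial germ cell-like classes, the shares of these classes and the tests of 26 gene lists, all fixed before the data were examined, were therefore not run, since 0 of their 628 genes could be matched. Clusters were compared by number instead.

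Cells were kept with at least 100000 counts and 2000 detected genes, which left out 7 cells. Genes were divided at random into 2 sets (seed 1). The first, of 14300 genes, built the clusters, and the second, of 14292, was tested in and between clusters. No gene was thus both picked to define a cluster and tested in it, although all genes entered the scaling of each cell. Tests in whole collections used the genes of both sets. Counts were scaled to 10000 per cell and put on a log scale, the 2000 most variable genes of the first set were reduced to 20 components, and a graph of 15 neighbours was cut with the Leiden method (leidenalg 0.10.2, igraph 0.11.9). The planned resolution of 1 gave 17 clusters, none with 10 cells in more than 2 collections. A resolution of 0.3 was used instead, chosen on cell numbers before any gene was tested, after resolutions of 1, 0.6 and 0.3 with and without gene scaling had been looked at. No doublet caller was run, since the cells had been picked singly by hand.

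Cells are not replicates, so counts were summed per collection, or per collection and cluster. The labels do not say that collections came from separate embryos or cultures, so p-values measure only the spread between these collections, which may be technical. Sums entered edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05; R 4.3.3). The day entered as a number. Whole collections needed at least 10 kept cells (14 collections, with sums of 14136562 to 361719319 counts), and cluster trends 6 collections over 3 days with at least 5 cells. The planned minimum of 10 cells left no cluster with 6 collections. Clusters were compared with the other cells of their collections where both sides had at least 10 cells, with the collection as a block, which gave 4 collections for each of clusters 1 to 4 and none for clusters 5 to 8. Slopes of 2 clusters were compared without a block, although some collections entered both. DESeq2 1.42.0, limma 3.58.1 on the mean over cells of log2(CPM + 1), RLE factors, no filter, other cell minimums, a minimum of 4000 genes, a resolution of 0.6, collections without dots in their titles, each collection left out, no collection block, the B number as a block and 2 groups of days were the alternatives set beforehand. The depth covariate, total-count scaling, equal cluster weights, the removal of cluster 2 and the removal of ENSMFAG00000000004 were chosen after seeing the data. TMM factors in the cluster 2 comparison were 0.337 to 1.04 in cluster 2 and 1.33 to 1.96 in the other cells, so TMM-scaled CPM there is not a share of counts.

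IDs were named by a rule fixed before the data were examined: adjusted p under 0.05, a log2 fold change of at least 1 (0.1 per day for trends) and a mean log2 CPM of at least 5, then the largest fold changes. The rule asked for gene symbols, and since there were none it was applied to IDs, with at most 2 in each direction per comparison. Correlations, neighbours and distances between collections were tested with 100000 permutations (scipy 1.17.1). Genes per cell were compared at an expected depth of 100000 counts. The fits were tested on simulated counts with 200 changed IDs, all taken from IDs with a mean log2 CPM of at least 3. Counts were drawn for each ID alone from the model that edgeR fits, with no effect of a collection shared by IDs. The shares found can therefore be too favourable for these data, and they do not cover IDs of lower expression. Of the calls made there, unchanged IDs were 4.84% in whole collections, 8.97%, 8.06% and 5.26% for clusters 1, 2 and 3 by day, and 6.93%, 1.22%, 3.53% and 1.80% for clusters 1 to 4 against the other cells. They were 21.1% of 38 calls for the slopes of clusters 1 and 2, and 0 of 7 and 0 of 5 calls for clusters 1 and 3 and clusters 2 and 3. For clusters 1 to 4 against the other cells, fold changes of 3 log2 units were found in 45.5%, 25.8%, 31.8% and 66.7% of cases and of 6 units in 97.0%, 97.0%, 92.4% and 97.0%.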

Results

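Single cells of cynomolgus monkey (Macaca fascicularis) embryos kept in culture were profiled with SMART-seq2, a full-length RNA sequencing protocol for single cells, and each sample of the series was 1 cell. The titles of the samples gave the day (9, 11, 13, 15, 17, 19 or 20), a number after the letter B and a cell number. Of the analysed collections, the titles of E13 B1 also held the letters pe and those of E17 B1 the letter p. What the B number and these letters stood for was not given (an embryo, a batch or a dish, for example), and cells that shared a day and a B number are called a collection here. Of the 1154 samples of the series, 600 had a column of estimated counts over 28592 gene IDs, from 15 collections, and the other 554 were not analysed here. After cells under 100000 counts or under 2000 detected genes were left out, 593 cells remained: 36 at day 9, 57 at day 11, 94 at day 13, 121 at day 15, 139 at day 17, 62 at day 19 and 84 at day 20. Days 9, 13, 19 and 20 had 2 collections each, days 15 and 17 had 3, and day 11 had 1.

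Depth differed widely between cells and collections. The total count per kept cell ranged from 107155 to 18828693 with a median of 2660362, and between 2286 and 10650 genes were detected per cell. The median total count was lowest in collection E19 B2, at 583690, and highest in E09 B1, at 7778290. No cell had the same column as another cell. The gene IDs could not be paired with gene symbols, so no cell type, marker or gene list could be named, and IDs are given as deposited.

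The series asks how embryonic and extra-embryonic lineages are set apart. Because no lineage could be named, the cells were grouped by expression into 8 broad clusters, numbered by size, with 157, 120, 94, 91, 45, 36, 29 and 21 cells. Cluster 1 came from 10 collections, cluster 2 from 14, cluster 3 from 8 and cluster 4 from 11. Clusters 5 to 8 came mostly from 1 collection each: 80.0% of cluster 5 from E15 B1, 91.7% of cluster 6 from E17 B1, 69.0% of cluster 7 from E17 B5 and 66.7% of cluster 8 from E09 B2. All but 1 of the 21 cells of cluster 8 were from day 9. The cells were picked by hand, so the shares of clusters can follow the picking, and the shares were not tested against the day. Genes of the second random set, which entered the clustering only through the scaling of each cell, gave groups with an adjusted Rand index of 0.657 against these clusters. The index was 0.555 at a resolution of 0.6 and 0.518 at the resolution of 1 set beforehand. At 0.6 the best matches of clusters 1 to 4 shared about 50% of the cells (Jaccard index 0.522, 0.504, 0.543 and 0.494), so fits at that resolution compare other groups of cells.

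**Figure D1:**
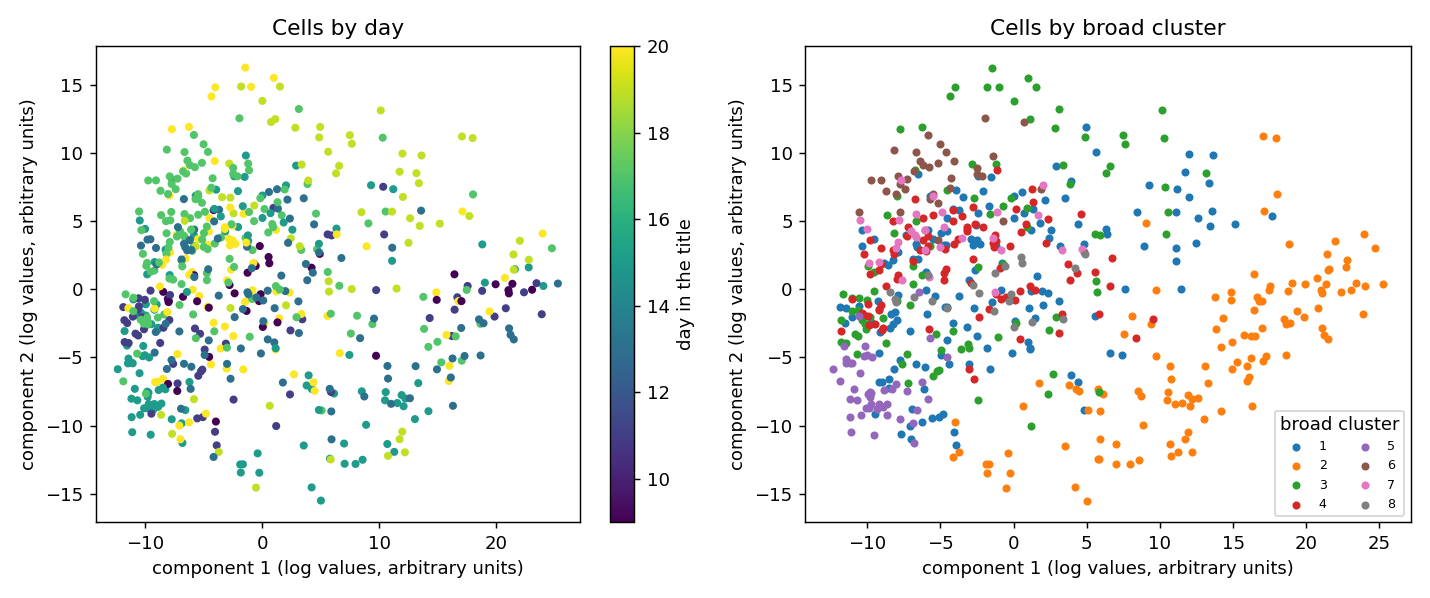
The 593 cells on the first and second principal components of the log values of the clustering genes, which held 13.0% and 6.02% of the variance, with axes in arbitrary log units. Each point is 1 cell, coloured by day on the left and by broad cluster on the right, and the cells of cluster 2 lie mostly at high values of component 1.

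**Figure D2:**
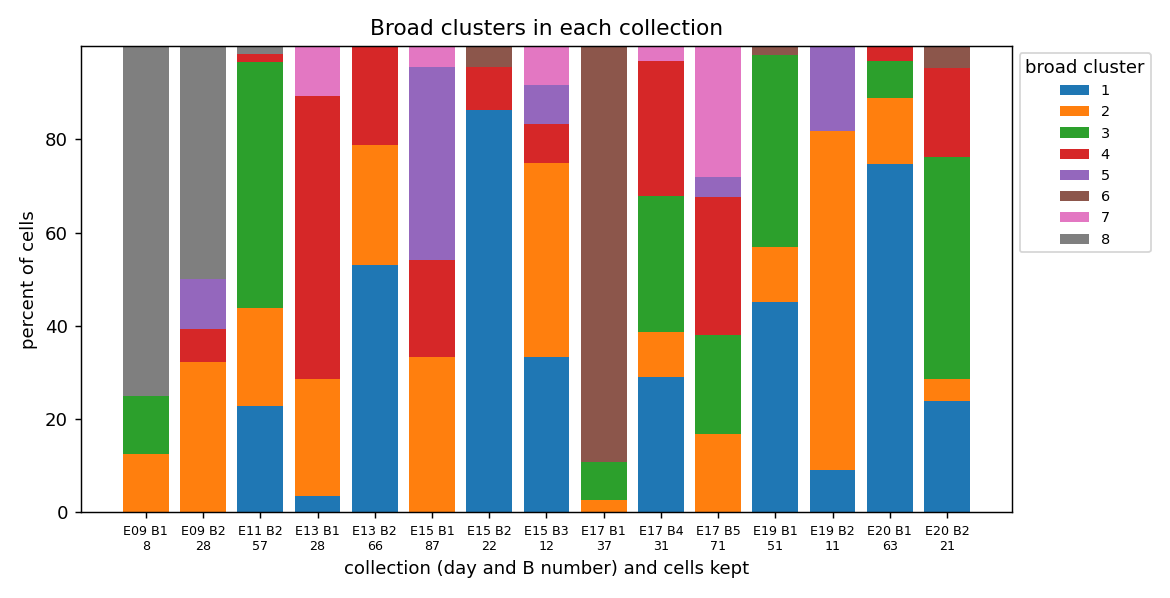
Percent of the kept cells of each collection (bars, with the number of cells under each) that fell in each of the 8 broad clusters. Cluster 6 filled 89.2% of collection E17 B1 and was at 0 in E17 B4 and E17 B5.

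Pooled over all cells, neighbours came more often from the cell's own collection than the numbers of cells give, and neighbours from other collections did not favour the same day. Of the 15 nearest neighbours of each cell, 58.1% came from the cell's own collection, against 8.93% from the numbers of cells alone. Among neighbours from other collections, 8.68% came from a collection of the same day, and permuting the days over the 15 collections gave 9.55% on average (one-sided permutation p = 0.556). The collections of day 9 went against the pooled value: E09 B1, with 8 cells, had 24.2% of its neighbours from itself and 59.2% from E09 B2, against 4.73% from the numbers of cells, and E09 B2 had 16.0% from E09 B1, against 1.35%. E15 B3 had 10.0% from itself and 18.9% from the other collections of day 15, against 18.4%. No test was run on single collections. The distance between collections, taken as 1 minus the correlation of their log2(CPM + 1) sums over 12912 genes, was 0.255 on average in 9 pairs of the same day and 0.248 in 82 pairs of other days. It was not related to the number of days between them (r = 0.0449 over 14 collections, one-sided permutation p = 0.378). Without the cells of cluster 2, an alternative chosen after seeing the data, r was 0.283 (one-sided permutation p = 0.0425).

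The number of genes detected at an equal depth of 100000 counts did not follow the day either. Over the 14 collections with at least 10 kept cells, the median number of detected genes had r = -0.112 (permutation p = 0.701) and rho = -0.0378 (permutation p = 0.898) with the day. Of 3 such relations, the number of genes that made up 50% of the counts had r = 0.265 (permutation p = 0.358) and rho = 0.122 (permutation p = 0.676), and the mean log10 total count had r = -0.0142 (permutation p = 0.961) and rho = 0.0445 (permutation p = 0.881). The lowest adjusted p in this family was 0.961 for r and 0.898 for rho. Without the collections E09 B2 and E11 B2, the farthest from the median day, r was 0.0329 for detected genes, -0.0227 for genes at 50% of the counts and 0.369 for the total count. Within the 12 collections whose titles held no dots, r was -0.159, 0.202 and -0.0338. The other title style, with dots, held 2 of the 14 collections, too few for a value.

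In whole collections edgeR's quasi-likelihood test on summed counts, with Benjamini-Hochberg adjustment, called 2 of 16002 gene IDs with the day, a number that 6 of 100 permutations of the days, the real order included, reached or passed. ENSMFAG00000033907 rose by 0.44 ± 0.07 log2 units per day (SE, n = 14 collections, adjusted p = 0.0294). Its TMM-scaled CPM was 10.6 in the collection of day 9, 24.5 at day 11, 36.1 and 43.8 at day 13, between 72.6 and 110.5 at day 15, and between 131.5 and 238.3 at day 17. At days 19 and 20 the collections lay apart, with 411.8 and 82.5 at day 19 and 142.3 and 457.9 at day 20. The adjusted p was between 0.00668 and 0.175 when each collection was left out in turn, and above 0.05 in 9 of the 14 cases, while the slope stayed between 0.41 and 0.47. The call also ended with the B number as a block (adjusted p = 0.187), without the collections with dots (0.125), with limma (0.156), with a minimum of 5 cells (0.129) and with 2 groups of days (1.00), and, in alternatives chosen after seeing the data, with total counts alone (0.0738), depth as a covariate (0.102) and equal cluster weights (0.517). The second ID, ENSMFAG00000045610, outside the rule for named IDs and chosen after its values were seen, was at 4.07 CPM at day 9, at 0.297 at day 11 and at 0.114 in E13 B2, and had no count in the other 11 collections. At an unadjusted p under 0.05, 903 IDs followed the day, where 800 would by chance. DESeq2 called 166 IDs.

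**Figure D3:**
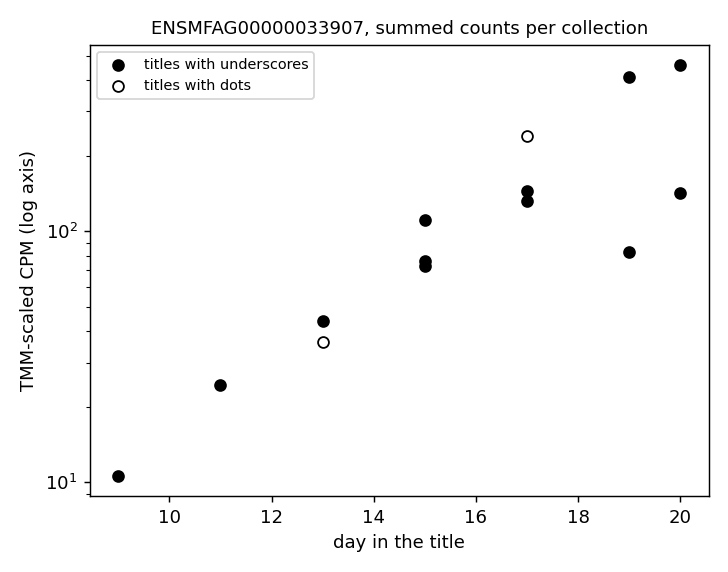
TMM-scaled CPM of ENSMFAG00000033907 on a log axis against the day in the title, 1 point for each of 14 collections, filled for titles without dots and open for titles with dots. The values went from 10.6 at day 9 to 457.9 in 1 of the collections of day 20.

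A test for any difference between days in whole collections called 0 of 18799 IDs with edgeR, and 701 IDs had an unadjusted p under 0.05, where 940 would by chance. DESeq2 called 257 and limma on mean log values called 4. The 0 was not stable in edgeR either: 67 IDs were called with cells of 4000 genes and 81 without a filter. Without the cells of cluster 2, an alternative chosen after seeing the data, 29 were called. It stayed at 0 with RLE factors, total counts alone and depth as a covariate. Within single clusters, with at least 5 cells per collection, edgeR called 0 of 6846 IDs with the day in cluster 1 (7 collections), 0 of 4744 in cluster 2 (10 collections) and 1 of 6228 in cluster 3 (6 collections). At an unadjusted p under 0.05 these clusters had 244, 448 and 115 IDs, where 342, 237 and 311 would by chance, and the smallest adjusted p in cluster 2 was 0.0543. DESeq2 called 68, 307 and 71, and limma 6, 3 and 1. The ID called in cluster 3, ENSMFAG00000035965, had a TMM-scaled CPM of 1145 in the only collection of day 11 and of at most 1.99 in the 5 collections of days 17 to 20 (adjusted p = 0.0358 with edgeR). The call ended without E17 B4 (adjusted p = 0.0736), E17 B5 (0.257), E20 B1 (0.483) or E20 B2 (0.079) and with the B number as a block (0.219). In alternatives chosen after seeing the data it ended with depth as a covariate (0.309) and total counts alone (0.0588). The slope was -1.885 log2 units per day in the main fit and between -1.795 and -2.164 in these refits. With 2 groups of days, where E11 B2 alone made up the early one, the call also ended, at -10.68 log2 units. Without E11 B2, the only collection where this ID was high, the ID was not among those tested and 0 IDs were called. ENSMFAG00000033907 had slopes of 0.28 ± 0.11, 0.73 ± 0.22 and 0.48 ± 0.22 per day (SE) in clusters 1, 2 and 3, and its adjusted p by edgeR was 0.999, 0.314 and 1.00. Counts were also simulated with 200 changed IDs, all at a mean log2 CPM of at least 3. Slopes of 0.2, 0.5 and 1 per day were then found in 10.3%, 75.8% and 92.4% of cases in whole collections. Slopes of 0.5 were found in 28.8%, 12.1% and 27.3% of cases in clusters 1, 2 and 3, and slopes of 1 in 77.3%, 74.2% and 80.3%.

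Each of clusters 1 to 4 was then compared with all other cells of the same 4 collections, at IDs of the second random set of genes, with the collection as a block. In cluster 4, 226 of 7548 IDs differed at an adjusted p under 0.05 (edgeR), 111 of them higher and 115 lower. ENSMFAG00000001837 was higher by 7.89 ± 0.41 log2 units (SE, adjusted p = 0.000921, edgeR), with TMM-scaled CPM of 125.3 ± 177.6 in cluster 4 and 0.489 ± 0.627 in the other cells (SD, n = 4), higher in 4 of 4 collections. ENSMFAG00000042357 was lower, by -7.64 ± 0.64 (SE, adjusted p = 0.00445, edgeR), with 0.713 ± 0.705 against 105.1 ± 69.7 CPM (SD, n = 4), in 4 of 4 collections. ENSMFAG00000000722 was higher by 7.64 ± 0.75 (SE, adjusted p = 0.0106, edgeR), in 3 of 4 collections, and ENSMFAG00000000205 lower, by -6.97 ± 1.13 (SE, adjusted p = 0.0236, edgeR), in 4 of 4. The fall of ENSMFAG00000000205 lost the call with cells of 4000 genes (adjusted p = 0.0883), at a resolution of 0.6 (0.148), with limma (0.0538), without the collections with dots, here E13 B1 alone (0.0942), without E13 B2 (0.0904) and without E17 B5 (0.0823), at -5.08 log2 units at 0.6, -1.02 with limma and between -6.15 and -7.12 in the rest. The rise of ENSMFAG00000000722 lost it without E15 B1 (0.193) and without the block (0.0835), at 6.77 and 8.09. With limma 557 IDs were higher and 133 lower. With E13 B1, E13 B2, E15 B1 or E17 B5 left out, 92, 81, 62 or 87 IDs passed.

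In cluster 3, 57 of 7277 IDs differed (edgeR, adjusted p under 0.05), 10 higher and 47 lower than in the other cells. The balance was the opposite with limma, at 820 higher and 86 lower. ENSMFAG00000038308 was higher by 7.22 ± 0.84 log2 units (SE, adjusted p = 0.0243, edgeR), at 240.5 ± 176.3 against 3.01 ± 3.21 CPM (SD, n = 4), and ENSMFAG00000018546 by 7.12 ± 0.83 (SE, adjusted p = 0.0243, edgeR). ENSMFAG00000044238 was lower, by -8.70 ± 0.79 (SE, adjusted p = 0.0124, edgeR), at 0.181 ± 0.213 against 72.1 ± 87.9 CPM (SD, n = 4), and ENSMFAG00000032399 by -8.22 ± 1.14 (SE, adjusted p = 0.0405, edgeR). All of these moved the same way in 4 of 4 collections. In the order given, all 4 lost the call at a resolution of 0.6 (adjusted p = 0.697, 0.198, 0.206 and 0.124, at 2.81, 6.58, -8.49 and -6.85 log2 units) and without the block (0.0983, 0.189, 0.117 and 0.0981, at 6.26, 7.17, -8.67 and -7.05), where 0 IDs passed. The first ID thus lost most of its fold at 0.6, and the others lost the call with folds of 6.58 units or more in size. Without E11 B2 only ENSMFAG00000044238 kept it, and ENSMFAG00000032399 also lost it without E20 B2 (0.0537) and with total counts alone (0.056). No ID passed without E17 B5 or without E19 B1, when 18 and 31 IDs passed without E11 B2 and E20 B2. In cluster 1, 1 of 7342 IDs passed, and 622 IDs had an unadjusted p under 0.05, where 367 would by chance. The ID called, ENSMFAG00000032300, was lower by -9.465 ± 0.745 log2 units (SE, adjusted p = 0.0321, edgeR). It was at 0.128 ± 0.178 against 96.5 ± 134.6 TMM-scaled CPM (SD, n = 4). In the other cells it was at 286.2 CPM in E11 B2 and 98.2 in E20 B1, but at 1.41 in E19 B1. In E13 B2 it had 0 counts against 1. This ID lost the call without the block (adjusted p = 0.506, at -9.521 log2 units) and with total counts alone (0.0653, at -9.352). It also lost it with cells of 4000 genes (0.123, at -9.223), where the match of cluster 1 shared only 82 of its 142 such cells. No ID passed without E11 B2 or without E20 B1, and 3 and 2 passed without E13 B2 and E19 B1.

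In cluster 2, 71 of 7979 IDs differed (edgeR, adjusted p under 0.05), 67 higher and 4 lower. ENSMFAG00000009591 was higher by 7.66 ± 0.83 log2 units (SE, adjusted p = 5.23e-08, edgeR) and ENSMFAG00000000002 by 6.36 ± 0.40 (SE, adjusted p = 4.42e-15, edgeR), both in 4 of 4 collections. ENSMFAG00000037651 was lower, by -3.76 ± 0.96 (SE, adjusted p = 0.0467, edgeR), in 3 of 4 collections, and ENSMFAG00000039111 lower, by -3.56 ± 0.79 (SE, adjusted p = 0.015, edgeR), in 3 of the 4, with 0 counts against 1 in E11 B2. Both falls lost the call with RLE factors in edgeR (adjusted p = 0.126 and 0.0981, with 0 lower IDs in all), with DESeq2 (adjusted p = 0.189 and 0.173), at a resolution of 0.6 (0.794 and 0.792), without the block (0.576 and 0.482), without E15 B1 (0.461 for both) and with limma, where they were at -0.28 and -0.06. The fall of ENSMFAG00000037651 also lost it with cells of 4000 genes (adjusted p = 0.0608, at -3.884 log2 units), without E13 B2 (0.0677, at -3.787) and without E17 B5 (0.143). In the first 2 of these the fall was thus no smaller than in the main fit. The balance of directions in this cluster was not stable. The median ID lay at -0.73, and with a minimum of 5 cells it lay at -1.46, with 91 IDs higher and 425 lower. With scaling to total counts alone, added after the data were seen, it lay at -2.24, with 77 higher and 1408 lower. With total counts alone the 4 named IDs were at 6.15, 4.79, -5.16 and -4.99. Without E15 B1 or E17 B5, 31 and 25 IDs passed with TMM.

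Cluster 2 also stood apart in 1 ID and had the lowest depth, with cluster 6 near it. The 120 cells of cluster 2 had a median total count of 705834, against 953026 in cluster 6 and 2443410 to 5194740 in the rest. A median of 15 genes made up 50% of a cell's counts in cluster 2, against medians of 116 to 214 genes in the other 7 clusters. ENSMFAG00000000004, singled out after its values were seen, was the most abundant ID in 432 of the 593 cells and took 6.24% of the counts of the median cell. It took 26.4% in the median cell of cluster 2, and over 50% in 19 cells, all of them in cluster 2. In the 9 collections with at least 5 cells on both sides, its median share was higher in cluster 2 by 26.2 ± 11.8 percentage points (SD, n = 9), in 9 of 9 (no test, since the ID was chosen on these cells). E19 B2 had too few other cells for this comparison. There 8 of 11 kept cells were in cluster 2, and their median share was only 6.34%. ENSMFAG00000000002 was looked at because it had been called higher in 4 of these 9 collections, and its share, also without a test, was 0.158 ± 0.036% in the other cells and 2.76 ± 2.10% in cluster 2 (SD, n = 9). The log10 of the median total count was lower in cluster 2, by -0.675 ± 0.171 (SD, n = 9), in 9 of 9, again without a test, since the low depth had drawn attention to the cluster.

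**Figure D4:**
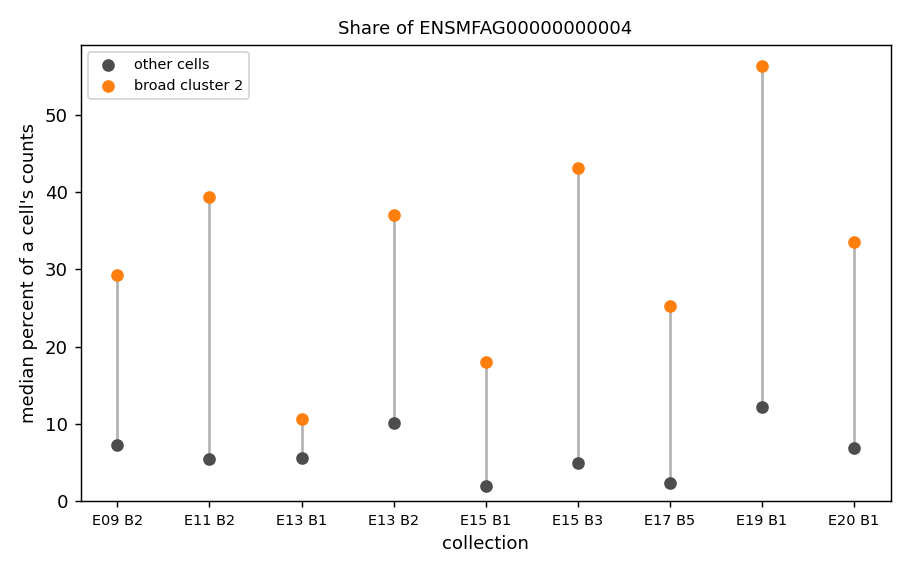
Median percent of a cell's counts taken by ENSMFAG00000000004 in broad cluster 2 (orange) and in the other cells (grey) of each of 9 collections, joined by a line. Cluster 2 was higher in 9 of 9 collections, from 10.7% against 5.61% in E13 B1 to 56.3% against 12.2% in E19 B1.

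Whether the change with the day differed between clusters was tested in edgeR as a cluster by day term. No ID passed for clusters 1 and 2 (7222 IDs), 1 and 3 (7400 IDs) or 2 and 3 (6946 IDs). At an unadjusted p under 0.05 there were 412, 202 and 302 IDs, where 361, 370 and 347 would be so by chance. DESeq2 called 7, 62 and 81 IDs and limma 0 in each. The simulated slope differences of 1 per day were found in 42.4%, 9.09% and 7.58% of cases. Each simulated change also moved the level of 1 cluster far from the other. These shares therefore do not tell how often a slope difference of that size alone would be found. How many such changes the tests missed is not known.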

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

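The tests of clusters 2 and 6 below were chosen after their results were seen, and the depth covariate, its judgement by the slope and the equal cluster weights were chosen after seeing the data. Of 18 groups of 4 to 10 values given Dixon's test, 1 held a value far from the others, and chance gives about 5% of groups. The share of ENSMFAG00000000002 was 7.43 percentage points higher in cluster 2 than in the other cells of collection E13 B2, against 0.565 to 3.87 points in the other 8 collections.

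Cluster 2 combined few counts with a high share of 1 ID. A low number of reads alone is argued against: after every cell was thinned to 100000 counts, the Jaccard index of the cluster with its thinned match was 0.992. Thinning evens out reads and not the RNA that each library held, so it cannot decide on the latter. At an expected depth of 100000 counts, cluster 2 had a median of 2522 detected genes, against medians of 3448 to 5964 in the other clusters. The dominant ID as the cause through scaling is also argued against, for that ID alone, since without it before scaling the index was 0.825. Other abundant IDs stayed in the totals, such as ENSMFAG00000000002, at 2.76% in cluster 2 and 0.158% in the other cells. Scaling by several abundant IDs together was not tested. What remains open includes damaged or dying cells and a cell state with little RNA. No biological explanation was tested, since the labels name no such group.

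Cluster 6 held 33 of 37 cells of collection E17 B1, or 89.2% (exact 95% interval 74.6% to 97.0%). The median total count of cluster 6 was 953026, the lowest after cluster 2. A low number of reads as the cause is argued against, since the Jaccard index of the cluster after thinning was 1. Thinning bears on the number of reads only. The other collections of day 17 held 0 of 31 and 0 of 71 cells, with upper exact bounds of at most 11.2%, and E13 B1, the other analysed collection with dots in its titles, held 0 of 28, with an upper bound of 12.3%. These bounds cover the counting of cells and not the spread between collections or the picking by hand, so 1 or 2 collections exclude neither the day nor the batch of titles with dots. These, a batch of that collection alone, the cells chosen in it and a difference between embryos stay open.

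The 2 IDs that followed the day in whole collections did not stand beyond chance: 6 of 100 draws of days over collections, the real one included, gave at least 2 IDs, and the highest other draw gave 28. Structure among the collections other than the day may underlie a draw of 28, but only 1 draw reached it and this was not tested. With the mean log10 total count as a covariate neither ID kept its call (adjusted p = 0.102 for both, edgeR). This outcome had been written down beforehand for depth as the cause, although the covariate itself was chosen after seeing the data. For ENSMFAG00000033907 the slope was 0.44 ± 0.07 without and 0.44 ± 0.07 with the covariate (SE, edgeR), so the call ended without a smaller slope. Over the 14 collections the covariate had an r of -0.0142 with the day, so a linear effect of mean depth could hardly make or move that slope. The unchanged slope, a measure chosen after it was seen, thus adds nothing to this r. Without E09 B2 and E11 B2 the r was 0.369, but no slope was fitted without both, so this r does not decide. Only a linear effect of mean depth was looked at, and other effects of depth are not excluded. With equal weight for each cluster that ID had a slope of 0.50 ± 0.12 (SE, limma, adjusted p = 0.517). Only clusters with at least 5 cells in a collection were averaged, so the clusters averaged still differed between collections. This slope therefore does not decide whether a few clusters set its sums. ENSMFAG00000045610 had 0 counts in 11 of 14 collections. Its slopes were -1.23 ± 0.19 with depth (SE, edgeR) and -0.0052 ± 0.056 with equal weight (SE, limma). Neither decides: the ID is near the floor, and on log2(CPM + 1) an ID under 1 CPM in most collections gives a slope near 0 in any case.

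The ID called in cluster 3 had 4 of 100 draws with at least 1 ID, the real one included, and the highest other draw gave 1. For this trend taken alone the share is just under 0.05, too near it for a verdict on 100 draws. Once the 4 trends that were run are counted it is no longer under 0.05, so chance is not excluded. The ID was high only in E11 B2, the only collection of day 11, so the day and that collection cannot be told apart. It lost its call in 8 of 16 refits. The refit without the collections with dots is among the 16, and it repeated the main fit, since none of them entered this trend. A further refit without E11 B2 did not test the ID and called 0 IDs. Where 0 IDs were called no draws were made. For the clusters compared with other cells, 4 collections make 8 sign splits, too few for a share under 0.05. The real split gave 1, 71, 57 and 226 IDs in clusters 1, 2, 3 and 4, and the highest of the other splits 0, 8, 0 and 0. In each comparison only 1 split, the real one, gave as many.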

How the results depend on the processing

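Values are given for the day in whole collections (2 IDs), any difference between days (0), the day in clusters 1, 2 and 3 (0, 0 and 1), and clusters 1, 2, 3 and 4 against the other cells (1, 71, 57 and 226). The causes were not tested, unless fewer samples or genes are named. With DESeq2 the counts were 166, 257, 68, 307 and 71 for the days, 652, 807, 974 and 1312 for the clusters, and 7, 62 and 81 for slopes between clusters 1 and 2, 1 and 3, and 2 and 3, which edgeR gave as 0. With limma on mean log values they were 7, 4, 6 and 3 for the first 4, and 122, 3218, 906 and 690 for the clusters, of which 3182, 86 and 133 were lower in clusters 2, 3 and 4. RLE factors kept every count within 1.5 times, although cluster 2 then had 94 higher and 0 lower. Total counts alone gave 1 in whole collections, 4 and 0 in clusters 2 and 3 by day, and 0, 1485 and 30 in clusters 1, 2 and 3 against other cells. Without a filter 6, 81, 106 and 2 IDs passed for whole collections, any difference, and clusters 2 and 3 by day. A minimum of 5 cells gave 18 and 1 for whole collections, and 2, 516 and 313 for clusters 1, 2 and 3, with 425 of the 516 lower. Cells with 4000 genes gave 67 for any difference, 1 and 4 for clusters 1 and 2 by day, and 58, 37 and 98 for clusters 1, 2 and 4. These cells were clustered anew, and the match of cluster 1 shared 82 of its 142 such cells (Jaccard index 0.5655). The fits of cluster 1 in this setting thus compare another group of cells. A resolution of 0.6 gave 3 for cluster 2 by day, and 21, 0 and 62 for clusters 2, 3 and 4, and had no result for cluster 3 by day or cluster 1 against other cells, for lack of collections. Without the collections with dots, and so with fewer samples, 0 IDs followed the day, 3 differed between days, and 92 passed in cluster 4. Without the collection block 0, 7, 0 and 143 passed. Days 9 to 13 against days 17 to 20 gave 0 in whole collections and 0 in cluster 3.

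The B numbers were not shown to pair collections: the differences between B1 and B2 within a day had correlations of -0.157 to 0.0332 between days 13, 15, 19 and 20. With the replicate block, 1 ID in whole collections, 4 for any difference, 3 in cluster 2 and 0 in cluster 3 passed, and cluster 1 and the slope tests stayed at 0.

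Of the alternatives chosen after seeing the data, depth as a covariate gave 0 in whole collections, 20 in cluster 2 and 0 in cluster 3, the removal of cluster 2 gave 4 and 29 in whole collections, and equal cluster weights gave 0 for the trend. Removing ENSMFAG00000000004 kept every count within 1.5 times. The distance between collections had r = -0.00336 with the days apart without dots, and 0.283 without cluster 2, where it passed. It was 0.245 (one-sided permutation p = 0.0788) with 4000 genes per cell and 0.153 (p = 0.155, permutation) on mean log values, against 0.0449.

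Leaving out each collection in turn gave 0 to 3 IDs in whole collections, 0 to 11 for any difference, 0 to 1, 0 to 15 and 0 to 1 in clusters 1, 2 and 3 by day, 0 to 3, 25 to 78, 0 to 31 and 62 to 92 in clusters 1, 2, 3 and 4, and 0 to 1 for the slopes of clusters 2 and 3. The r of distance was -0.0780 to 0.130, that of detected genes -0.160 to -0.00341, and same-day neighbours made up 5.14% to 11.5%. The 15 IDs named by the rule kept their direction in all 235 refits that tested them and lost the call in 75. ENSMFAG00000000002, ENSMFAG00000009591, ENSMFAG00000001837 and ENSMFAG00000042357 kept it in every refit. These tallies hold some refits that could not differ. No collection with dots entered clusters 1, 2 and 3 against the other cells or cluster 3 by day. The refit without dots therefore repeated the main fit there. In cluster 4 it was the same fit as the one without E13 B1.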
